A study of Arabidopsis thaliana with 6 samples.

How the data were processed

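Small RNAs bound to ARGONAUTE1 (AGO1), the main effector protein of plant miRNAs and of many siRNAs, were isolated by immunoprecipitation from the aerial parts of 20-day-old Arabidopsis thaliana plants. Per the labels' protocols, plants spent 6 days on medium and 14 days on soil, and no treatment was applied. The series held 6 libraries, 2 from each of 3 genotypes: wild type (Col-0), the double mutant ein5 dcl4 and the triple mutant ein5 dcl4 dcl2. EIN5, also called XRN4, is a cytoplasmic exonuclease that degrades uncapped mRNA. DCL4 and DCL2 are Dicer-like nucleases that cut siRNAs from double-stranded RNA, and DCL2 is the maker of 22-nt siRNAs. The design text calls the replicates biological.

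The authors deposited 1 table of 32420 loci with 1 value per locus and genotype, and those values are used here as a signal in deposited units. Per the file headers the unit is TPM, but the 3 columns summed to 235535, 2404778 and 1743399, so the values were relative to a total that the sources used here do not give. Per the submitters' processing notes, Bowtie 1.2.2, SAMtools 1.9 and DESeq2 were named, with TAIR10 as the genome build and no role or order for each. Per the labels only the first read of each pair was used. Small RNA lengths, the treatment of reads that match several loci, strand and filters are not given in the sources used here. The authors' deposited table also held their log2 fold changes, p-values and adjusted p-values for ein5 dcl4 over Col-0 and for ein5 dcl4 over ein5 dcl4 dcl2. Over the 224 and 211 loci with a mean value of at least 100, the log2 fold changes of the authors' deposited table differed from the log2 ratio of their mean values by a median of 0.02 and 0.01.

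Each deposited value was the mean of the 2 libraries of a genotype. Every value above 0 could be written as a whole number of reads times 1 step plus a whole number of reads times another step, within a relative tolerance of 1e-14. This held for 15171, 15886 and 10092 loci in Col-0, ein5 dcl4 and ein5 dcl4 dcl2, which was 100% of the values above 0. The next best pair of whole numbers missed by 1.0e-12 or more. The reads of both libraries were recovered in this way. The recovered libraries are called library a and library b, since nothing ties them to a replicate number. Reads recovered per library were 1217707 and 957043 in Col-0, 1292727 and 836879 in ein5 dcl4, and 1102996 and 843408 in ein5 dcl4 dcl2. A read that matched several loci could be counted at each, so these totals may hold some reads more than once. One read was worth 0.185 and 0.257 units in Col-0, 1.92 and 2.79 in ein5 dcl4, and 1.71 and 1.90 in ein5 dcl4 dcl2. Precision was therefore lower in both mutants, where 3 reads, the upper limit that a count of 0 allows, came to 5.12 to 8.37 units against 0.555 and 0.770 in Col-0. Such limits cover counting error only, since the reads carried no molecular identifiers. Libraries of a genotype differed beyond sampling noise, with a chi-square per degree of freedom of 3.18, 5.26 and 5.82 over loci with at least 10 reads, and were counted as 2 samples.

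Loci were compared with limma 3.58.1 in R 4.3.3 on log2(value + 1), with a mean per genotype, all 6 libraries in 1 fit and a trended prior. The model had 3 residual degrees of freedom and 2.16 prior degrees of freedom. Loci with a mean of at least 1 unit over the 6 libraries were tested, 11376 in all, and called at a two-sided Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates changes of low loci. Where a group held 3 or fewer reads, values are given in place of a fold change. Gene lists were tested with limma's camera at a preset correlation of 0.01, over lists with at least 3 tested members. Shares of the table total were compared by an exact two-sided permutation test, which cannot give a p below 0.333 with 2 libraries against 2. The test, its threshold and filter, the gene lists and the rule for named loci were fixed before the data were examined. The rule took, per comparison, the 10 largest increases and the 10 largest decreases among called loci with a mean of at least 10 and no overlap between the libraries compared. It added the siRNA loci of the study, the mutated loci, and up to 4 members with the smallest adjusted p from every other list.

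The steps were tested on simulated reads before use, with 200 loci changed per comparison at a base level of at least 5 units. Base levels were means over the genotypes, so fewer loci passed the filter than in the data. Noise was set by 1 dispersion of 0.0107, taken from loci with a mean of at least 50 reads with the most variable loci left out. False calls at loci with fewer reads were thus not tested at their own spread. In the comparison of ein5 dcl4 with Col-0, 46% of loci changed 4-fold and 74% of loci changed 16-fold were recovered, with 0 false calls among 6920 loci. The shares were 43% and 75% with 2 false calls among 6976 loci for ein5 dcl4 dcl2 against ein5 dcl4, and 50% and 80% with 0 false calls among 6864 loci for ein5 dcl4 dcl2 against Col-0.

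Names and biotypes came from the TAIR10.1 annotation, matched by identifier for 31722 loci and unmatched for 698. That build is not the authors', so no coordinates are printed. The annotation and sequence also gave loci that overlap each other and the percent of a locus's exonic 21-mers that occur elsewhere in the genome. The planned lists of transposable element genes and structural RNAs could not be formed from this annotation, and pseudogenes were used as a class in their place, a choice made after the data were seen. The 8 TAS loci are not analysed here.

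Other settings, fixed before the data were examined, were another pseudocount (0.1 or 5), no filter or a mean of at least 10, trimmed-mean rescaling, an equal miRNA total, a prior without trend, only the 2 genotypes compared, an added 2-fold rule, each library left out in turn, an estimated correlation in list tests, and shares without the 10 largest loci. Added after the data were seen were limma's voom on the recovered reads, an equal table total, reads thinned to the same value per read, the authors' adjusted p-values, a fit restricted to loci without a repeated 21-mer, and list tests against protein-coding loci alone. A count test on the recovered reads and a replicate block were intended and not run. The tests were designed for values per library, and the deposited means were split into such values first. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were also used.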

Results

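AGO1-bound small RNAs were compared between wild-type Col-0, ein5 dcl4 and ein5 dcl4 dcl2 plants, with 2 libraries per genotype and 836879 to 1292727 recovered reads per library. Values are small RNA reads assigned to a locus in deposited units, not levels of its mRNA. The first comparison asked which loci had more or fewer AGO1-bound small RNAs when mRNA decay by EIN5 and siRNA production by DCL4 are both lost. The second asked which of these need DCL2, and the third what differed from wild type without DCL2. All 6 libraries came from AGO1 immunoprecipitation, so loading onto AGO1 cannot be told apart from the abundance of a small RNA.

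The mutated loci were checked first. EIN5 held 26 and 5 reads in the Col-0 libraries, 0 and 1 in ein5 dcl4, and 0 in both ein5 dcl4 dcl2 libraries. DCL4 held 0 and 4 reads in Col-0, 4 and 8 in ein5 dcl4, and 4 and 2 in ein5 dcl4 dcl2, and DCL2 held at most 2 reads in any library. DCL4 was called higher in ein5 dcl4 than in Col-0 (limma adjusted p 0.0146), a call that ended without Col-0 library a or b (adjusted p 0.119 or 0.0739), without ein5 dcl4 library b (0.0824) and with trimmed-mean rescaling or equal table totals. Small RNAs were too few at all 3 loci to check the genotypes.

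The makeup of the AGO1-bound pool differed between the genotypes. In Col-0, miRNA loci made up 66.9% ± 1.91 (SD, n = 2) of the table total, protein-coding genes 15.2% ± 0.917 and pseudogenes 16.1% ± 0.901. In ein5 dcl4, protein-coding genes took 94.6% ± 0.750 and miRNA loci 4.25% ± 0.783. The 2 nitrate reductase genes NIA1 and NIA2 alone held 47.7% ± 0.630 of the total there, against 0.00683% ± 0.00404 in Col-0. In ein5 dcl4 dcl2, miRNA loci held 96.2% ± 0.347, protein-coding genes 1.44% ± 0.133 and the NIA pair 0.00962% ± 0.00668. Each class share of miRNA loci, protein-coding genes and pseudogenes lay apart between genotypes in every library, and the exact permutation p was 0.333, the smallest that 2 libraries against 2 allow. Leaving out the 10 loci with the largest values, among them NIA1, NIA2 and 3 MIR166 loci, left miRNA loci at 35.3% in Col-0 and protein-coding genes at 93.1% in ein5 dcl4. The 3 MIR166 loci had nearly equal means, so reads that match all 3 may be counted at each and raise the miRNA shares.

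**Figure D1:**
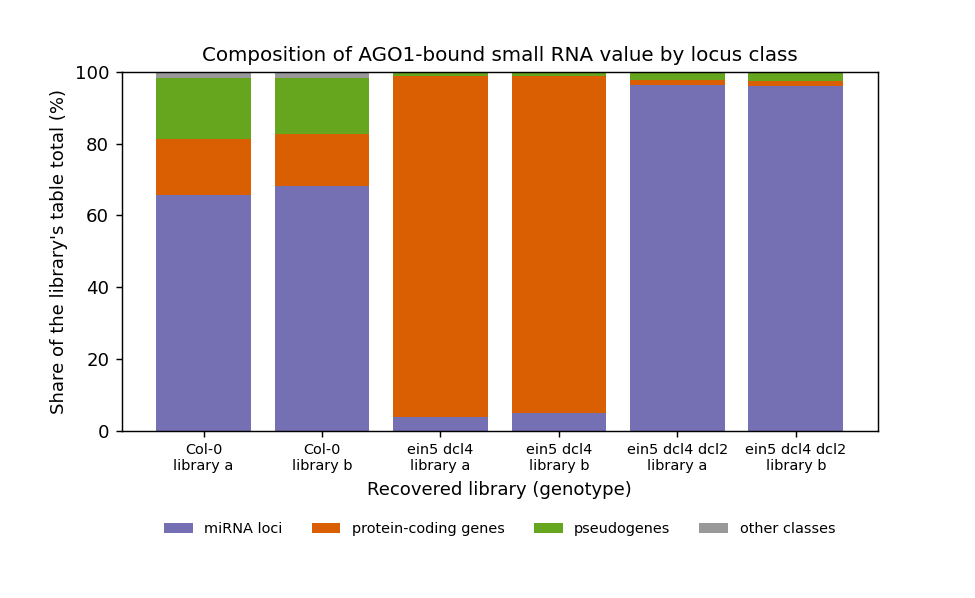
Stacked bars give the share of each recovered library's table total (%, from 0 to 100) held by miRNA loci, protein-coding genes, pseudogenes and all other classes, 2 libraries per genotype. Protein-coding genes fill 94.0% and 95.1% of the ein5 dcl4 bars, and miRNA loci fill 96.0% and 96.4% of the ein5 dcl4 dcl2 bars.

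Small RNAs from the nitrate reductase genes NIA1 and NIA2 rose from low levels in Col-0 to the highest values of all loci in ein5 dcl4. NIA1 (AT1G77760) went from 6.61 ± 4.27 to 530738 ± 30519 units (SD, n = 2), a log2 difference of 16.21 ± 0.54 (SE). NIA2 (AT1G37130) went from 9.19 ± 4.29 to 616729 ± 32466 units, a log2 difference of 15.95 ± 0.53. The limma adjusted p was 0.000170 for both. SMXL5 (AT5G57130) and SMXL4 (AT4G29920), relatives of the strigolactone signalling repressors, held 42649 ± 986 and 10935 ± 287 units in ein5 dcl4 against 0.349 ± 0.232 and 0.955 ± 0.827 in Col-0.

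These 4 loci are the siRNA loci of the study itself, so their direction here is not independent evidence. All 4 were called higher over all loci and adjusted over the list alone. The list's camera adjusted p was 0.000453, and the adjusted p = 0.0704 with an estimated correlation. NIA1 and NIA2 shared 0% of exonic 21-mers with each other, as did SMXL4 and SMXL5.

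Among the 10 largest increases were also chaperone genes. HSP70 (AT3G12580) held 64161 ± 4780 units in ein5 dcl4, HSC70-1 (AT5G02500) 55955 ± 4273, HSP90.1 (AT5G52640) 32199 ± 2390 and the HSP70-family gene AT3G09440 28086 ± 778. In Col-0 the same loci held 3 and 2, 17 and 8, 4 and 0, and 1 and 2 reads. The bromodomain gene GTE2 (AT5G10550) rose by 14.15 ± 0.61 on the log2 scale to 64103 ± 5060 units. DGAT3 (AT1G48300), an acyltransferase gene of oil synthesis, reached 44968 ± 2034 units, and CYP79B2 (AT4G39950), an enzyme of the indole glucosinolate pathway, reached 25090 ± 1791, from 3 reads in each and 1 read in each Col-0 library. Limma adjusted p for these loci ran from 0.000101 to 0.000557. AT3G09440 and GTE2 overlap a neighbouring gene, and 8.23% of the exonic 21-mers of HSC70-1 occur elsewhere, so some of their reads can belong to other loci.

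In the SMXL family 7 of 8 tested members rose, in every rescaling tried at least 7, and SMXL7 held 2556 ± 156 units against 3 and 0 reads in Col-0. In nitrate uptake and assimilation 7 of 7 tested members rose. Besides the NIA pair these included nitrite reductase NIR1 at 122 ± 19.2 units against 0.919 ± 0.515 and glutamate synthase GLU1, which overlaps a neighbouring gene, at 31.6 ± 1.33 against 0.606 ± 0.595. GLN1;1 and GLN2 rose on few reads, 2 and 1 against 0 and 0 in Col-0, and 5 and 4 against 3 and 1. With fewer than 10 reads a gain cannot be told apart from scaling. With trimmed-mean rescaling or equal table totals, 4 of 6 tested nitrate members rose. Camera adjusted p were 0.000745 for the SMXL family and 0.00192 for the nitrate list, and both were adjusted p = 0.0704 with an estimated correlation. Adjusted over the list alone, 7 members rose in both lists. Each list holds 2 of the siRNA loci of the study, which are not independent evidence. NIR1 no longer passed without Col-0 library a or b (limma adjusted p 0.0573 or 0.0519), and GLU1 without library a (0.0564).

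Among miRNA target mRNAs 14 of 22 tested members rose and 8 did not pass, with 14 also when adjusted over the list alone, beside 4341 of all 7833 protein-coding genes tested. The median log2 difference was 2.55 for the list and 2.13 for all protein-coding genes. AGO2, a target of miR403, rose by 4.38 ± 0.30 on the log2 scale, from 15.9 ± 2.13 to 357 ± 86.2 units. TOE1, MYB33 and SCL6, targets of miR172, miR159 and miR171, reached 46.7 ± 1.02, 17.4 ± 2.97 and 88.1 ± 5.49 units. In reads, TOE1 held 5 in each Col-0 library against 24 and 17 in ein5 dcl4, MYB33 5 in each against 8 and 7, and SCL6 30 in each against 44 and 33. One read was worth 0.185 and 0.257 units in Col-0 and 1.92 and 2.79 in ein5 dcl4. The rises of MYB33 and SCL6 thus rest largely on the deposited scaling. The list's camera adjusted p was 0.00192, but 0.162 against protein-coding loci alone, and the adjusted p = 0.0704 with an estimated correlation. With trimmed-mean rescaling 7 members rose and 1 fell, and with equal table totals 5 rose and 4 fell. SCL6 no longer passed without Col-0 library a or b (limma adjusted p 0.0600 or 0.0516), and MYB33 without library a (0.0517).

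Of the RNA silencing and decay genes 6 of 10 tested members rose, over all loci and adjusted over the list alone. EBF1, an F-box regulator of ethylene signalling, rose by 3.83 ± 0.43 on the log2 scale, and its relative EBF2, which overlaps a neighbouring gene, held 6 and 3 reads against 1 and 0 in Col-0. Of all 7833 protein-coding genes tested 4341 rose. This list's camera adjusted p was 0.0970, and 0.722 against protein-coding loci alone. With trimmed-mean rescaling 4 members rose and 1 fell, and with equal table totals 3 rose and 3 fell. EBF1 no longer passed without Col-0 library b (limma adjusted p 0.0542), nor EBF2 without library a or b (0.0517 or 0.0604).

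The pentatricopeptide repeat (PPR) genes, whose transcripts give phased siRNAs after miRNA cleavage in wild type, fell. Of 16 tested members 13 were lower and 3 did not pass, with 13 lower when adjusted over the list alone and 0 higher in any rescaling tried (limma unadjusted p under 0.05 for 0 higher and 14 lower). AT1G63080 fell by 5.11 ± 0.23 on the log2 scale, from 1588 ± 16.4 to 45.2 ± 7.06 units. AT1G62914 and AT1G63400 fell by 5.45 ± 0.42 and 5.08 ± 0.41. Limma adjusted p were 0.000389, 0.00163 and 0.00175. The list's camera adjusted p was 1.05e-13, and the adjusted p = 0.0669 with an estimated correlation. Of the exonic 21-mers of these 3 genes 32.9% to 70.6% occur elsewhere in the genome, so the reads of single members cannot be told apart with certainty.

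Of 11 other phasiRNA-producing genes tested 6 rose, and 7 rose when adjusted over the list alone, beside 4341 of all 7833 protein-coding genes. AT5G43740, a disease resistance gene with 27.2% repeated 21-mers that overlaps a neighbour, went from 154 ± 10.3 to 1164 ± 87.7 units, and the auxin receptor gene AFB2 from 35.2 ± 5.32 to 179 ± 1.09. For this list the camera adjusted p was 0.0970, and 0.722 against protein-coding loci alone. The direction depended on scaling, since with trimmed-mean rescaling 1 member rose and 3 fell, and with equal table totals 0 rose and 7 fell. AFB2 no longer passed without Col-0 library a (limma adjusted p 0.0520).

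Among miRNA loci 16 of 132 tested rose, 38 fell and 78 did not pass, with 16 and 36 adjusted over the list alone. The median log2 difference was -0.82 for miRNA loci and -0.79 for pseudogenes, and the summed value of miRNA loci was 3.91 and 4.40 times that of pseudogenes in the Col-0 libraries and 3.49 and 4.72 times in ein5 dcl4. MIR822, a young miRNA gene whose precursor is cut by DCL4, held 80.7 ± 26.3 units in Col-0 and 0 reads in both ein5 dcl4 libraries, which allows up to 5.75 and 8.37 units. MIR319b, a regulator of TCP genes, fell by 2.65 ± 0.15 on the log2 scale. MIR831 went the other way, from 47.2 ± 25.7 to 8944 ± 486 units with 15.2% repeated 21-mers, and MIR828 from 3.04 ± 0.673 to 69.4 ± 7.46. Camera gave an adjusted p of 1.05e-13 downward, and the adjusted p = 0.0704 with an estimated correlation. With trimmed-mean rescaling 82 fell and 5 rose, and with equal table totals 113 fell and 4 rose. Equal miRNA totals, which set the sum of this class by construction, gave 31 and 19.

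Of 15 photosynthesis mRNAs 11 rose in ein5 dcl4, and 13 adjusted over the list alone, among them CAB3 from 5.82 ± 0.115 to 123 ± 0.0992 units and LHCB2.1 from 1.01 ± 0.384 to 59.4 ± 2.76, with 42.6% and 42.9% repeated 21-mers. Camera gave an adjusted p of 0.000717, and the adjusted p = 0.142 with an estimated correlation. With trimmed-mean rescaling 6 rose and 0 fell, and with equal table totals 5 rose and 1 fell. Of 63 plastid genes 7 rose and 2 fell, and of 96 mitochondrial genes 4 rose and 8 fell, in counts that were 0 in both directions when adjusted over the list alone. With trimmed-mean rescaling 0 rose in either list while 10 and 52 fell, with equal table totals 0 rose while 38 and 98 fell, and with equal miRNA totals 19 plastid genes rose and 2 fell and 10 mitochondrial genes rose and 8 fell. Their camera adjusted p were 0.222 and 3.57e-07, the second with an adjusted p = 0.0669 with an estimated correlation. Pseudogenes were lower at 444 loci and higher at 23 of 2962 tested, and at 2104 and 2, 463 and 100, and 3057 and 1 loci with trimmed-mean rescaling, equal miRNA totals and equal table totals.

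In total 4401 loci were higher and 734 lower in ein5 dcl4 at a limma adjusted p under 0.05, and the median log2 difference of all 11376 loci was 1.49. Over loci with a mean of at least 10 it was -0.14, and with no filter 0.77. A read was worth more units in ein5 dcl4, so fewer reads there than in Col-0 passed a locus through the filter. This favours higher loci among those tested. Of the higher loci 4341 were protein-coding, and 2768 rested on fewer than 10 reads in both ein5 dcl4 libraries together. The authors' deposited table, which gave an adjusted p for 8518 loci, called 1635 loci higher and 76 lower at the same threshold. The counts were 2016 and 2948 with trimmed-mean rescaling, 6041 and 764 with equal miRNA totals and 1605 and 4738 with equal table totals, and 879 and 33 without Col-0 library a or 767 and 34 without Col-0 library b. With a mean of at least 10 they were 647 and 305, and thinned reads gave 410 lower. Voom gave 6826 higher, but it adds the same fraction of a read to every count, which is more units in ein5 dcl4. Of 53 named loci called here 19 and 17 no longer passed without these libraries.

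**Figure D2:**
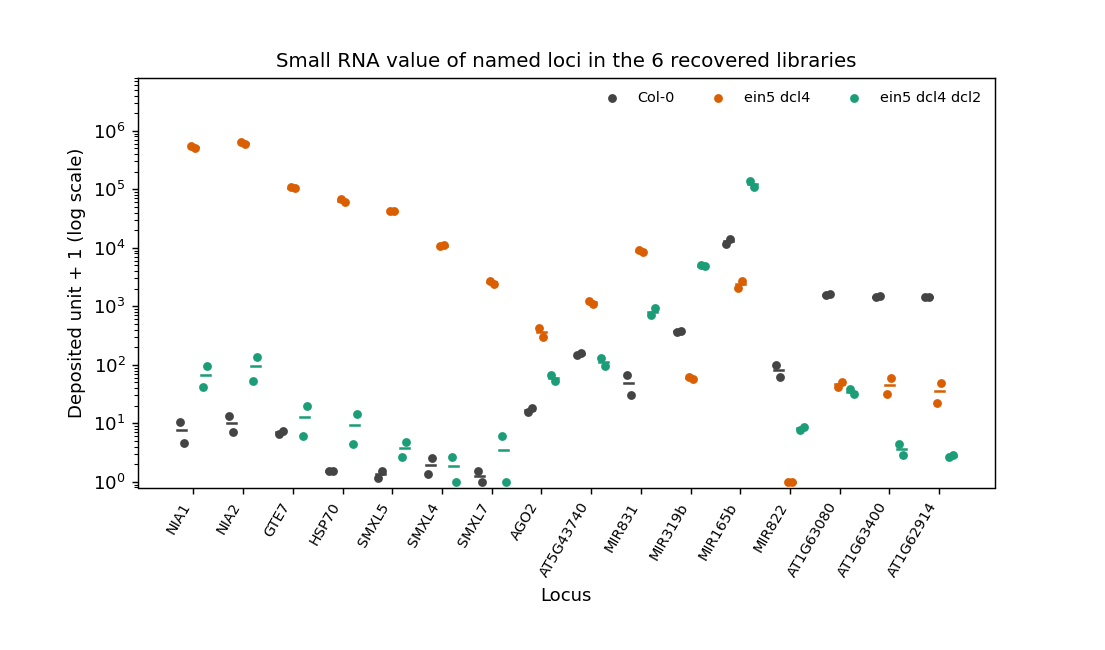
Points give the deposited units plus 1 (log scale) of 16 named loci in each of the 6 recovered libraries, coloured by genotype, and short lines give the mean of 2 libraries. NIA1 stood at 552318 and 509158 units in the ein5 dcl4 libraries and at 41.0 and 93.1 in ein5 dcl4 dcl2, and the PPR gene AT1G63400 had a mean of 1463 units in Col-0 and 44.6 in ein5 dcl4.

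The small RNAs with the largest gains in ein5 dcl4 were lower again in ein5 dcl4 dcl2, which also lacks DCL2. NIA1 fell by 13.04 ± 0.54 and NIA2 by 12.83 ± 0.53 on the log2 scale, to 67.1 ± 36.8 and 94.0 ± 60.5 units in ein5 dcl4 dcl2 (SD, n = 2, limma adjusted p 0.000363 for both). SMXL5 dropped to 1 and 2 reads and SMXL4 to 1 and 0 reads. GTE7 (AT5G65630), a bromodomain gene with 106906 ± 3851 units in ein5 dcl4, fell by 13.24 ± 0.56. HSP70, HSP90.1, AT3G09440 and Hsp70-2 (AT5G02490, with 13.1% repeated 21-mers) were among the 10 largest decreases as well, at 2 and 7, 1 and 6, 0 and 2, and 0 reads. GTE7 overlaps a neighbouring gene.

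The lists that had risen were lower. All 4 siRNA loci of the study, 7 of 7 nitrate genes, 7 of 8 SMXL genes and 15 of 22 miRNA target mRNAs were lower, and 4, 7, 7 and 20 when adjusted over the list alone. Those of the study's own choice are not independent evidence. The nitrate gene GLN1;1 held only 2 and 1 reads in ein5 dcl4 and 0 and 0 in ein5 dcl4 dcl2, and its call ended when single libraries were left out. Camera adjusted p were 0.00119, 0.00493, 0.00180 and 0.00119, and with an estimated correlation the adjusted p were 0.0892, 0.0984, 0.0892 and 0.0892. Against protein-coding loci alone the camera adjusted p of the nitrate genes and miRNA targets were 0.0522 and 0.0607. With trimmed-mean rescaling 3 of 6 nitrate genes, 6 of 7 SMXL genes and 11 of 22 targets were lower, with equal table totals 5, 6 and 10 of the same numbers, with equal miRNA totals 7 of 7, 8 of 8 and 22 of 24, and 0 members were higher in any of these. AGO2 fell by 2.57 ± 0.30 to 59.0 ± 10.8 units, and TOE1 and MYB33 held 0 reads. AT5G43740 fell by 3.38 ± 0.23, 1 of 7 other phasiRNA-producing genes that fell among 11 tested, over all loci and adjusted over the list alone (camera adjusted p 0.111), while with trimmed-mean rescaling 1 rose and 4 fell and with equal miRNA totals 11 fell. RNA silencing and decay genes were lower in 5 of 10 members, EBF1 among them, and in 6 adjusted over the list alone (camera adjusted p 0.0706). They were lower in 2 of 8 with trimmed-mean rescaling or equal table totals and 8 of 14 with equal miRNA totals. Of all 7833 protein-coding genes tested 3964 were lower. Against protein-coding loci alone the camera adjusted p were 0.485 for silencing and decay genes and 0.689 for other phasiRNA-producing genes.

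The PPR genes fell further. Of 16 tested members 10 were lower and 0 higher, over all loci, adjusted over the list alone and at an unadjusted limma p under 0.05, with a camera adjusted p of 0.00684, an adjusted p of 0.167 against protein-coding loci alone and an adjusted p = 0.199 with an estimated correlation. AT1G62910, AT1G63150, AT1G63330 and AT1G63070 held 0 reads in both ein5 dcl4 dcl2 libraries and 25.1 ± 7.86, 20.2 ± 6.91, 11.8 ± 3.09 and 8.97 ± 0.855 units in ein5 dcl4. A count of 0 allows up to 5.12 and 5.70 units there, and 47.0% to 96.1% of the exonic 21-mers of these 4 genes occur elsewhere.

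miRNA loci rose. Of 132 tested 111 were higher and 2 lower, with 115 and 2 adjusted over the list alone, and the camera adjusted p was 6.51e-50, with an adjusted p = 0.0496 with an estimated correlation. MIR319b went from 58.5 ± 3.89 to 4958 ± 65.1 units, a log2 difference of 6.38 ± 0.15, and MIR165b, a regulator of HD-ZIP III genes, from 2368 ± 410 to 122676 ± 19461, a difference of 5.70 ± 0.18. The limma adjusted p were 0.000156 and 0.000179. The related loci MIR169j, MIR169l and MIR169n held 136 ± 41.9, 132 ± 25.7 and 173 ± 56.9 units against 0 reads in ein5 dcl4, and 32.8% to 37.2% of their exonic 21-mers occur elsewhere. The 2 lower loci were MIR831, at 814 ± 152 units, and MIR156f, named after its value was seen. With equal miRNA totals, which sets the sum of this class by construction, 32 miRNA loci were higher and 23 lower.

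Of the photosynthesis mRNAs 7 of 15 fell, and 8 adjusted over the list alone, CAB3 to 15.4 ± 2.43 units, with a camera adjusted p of 0.0306, an adjusted p of 0.485 against protein-coding loci alone and an adjusted p = 0.242 with an estimated correlation. With trimmed-mean rescaling 4 of 14 fell and with equal miRNA totals 15 of 15. Plastid genes were higher at 11 and lower at 3 of 63 (4 and 3 adjusted over the list alone), with a camera adjusted p of 2.44e-05 and an adjusted p = 0.0551 with an estimated correlation, with 22 higher and 2 lower under trimmed-mean rescaling and 0 and 32 with equal miRNA totals. The plastid gene ATCG00020 went from 101 ± 26.6 to 386 ± 40.9 units, and turned lower with equal miRNA totals. Mitochondrial genes were higher at 11 and lower at 13 of 96 (8 and 10 adjusted over the list alone, camera adjusted p 0.0814), at 15 and 5 with trimmed-mean rescaling, 0 and 57 with equal miRNA totals and 8 and 8 with equal table totals. Pseudogenes were higher at 695 and lower at 84 loci, and at 1225 and 14, 68 and 1395, and 646 and 14 with trimmed-mean rescaling, equal miRNA totals and equal table totals.

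In total 1288 loci were higher and 4087 lower in ein5 dcl4 dcl2 than in ein5 dcl4 at a limma adjusted p under 0.05, with a median log2 difference of -1.33 over all loci. That median was -0.39 with a mean of at least 10 and -0.77 with no filter. The authors' deposited table, which gave an adjusted p for 4461 loci, called 186 higher and 683 lower. Of the lower loci 2515 rested on fewer than 10 reads in ein5 dcl4. The counts were 2001 and 1970 with trimmed-mean rescaling, 161 and 7755 with equal miRNA totals and 1115 and 1910 with equal table totals. With a mean of at least 10 they were 343 and 703, with only these 2 genotypes 631 and 2154, and voom and thinned reads gave 843 and 657 higher. They were 613 and 2156 without Col-0 library a, 609 and 2137 without Col-0 library b, and 846 and 842 higher without library a or b of ein5 dcl4 dcl2.

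Of the 4401 loci higher in ein5 dcl4 than in Col-0, 3743 were lower in ein5 dcl4 dcl2. This was 85.0% of the higher loci, against 35.9% or 1581 loci for independent lists. In 50 simulated sets of unchanged libraries no loci were called higher, so lists of the same share of loci were taken by rank of the limma t instead, a measure chosen after the data were seen. These shared a mean of 67.5% (66.2% to 68.6%). Both comparisons use the same ein5 dcl4 libraries, so part of the excess may come from them. Without Col-0 library a or b the overlap was 834 or 737, and in the authors' deposited table it was 642. It was 1561, 6036 and 1301 with trimmed-mean rescaling, equal miRNA totals and equal table totals, 610 with a mean of at least 10, and 2092 with only the 2 genotypes compared in each fit.

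**Figure D3:**
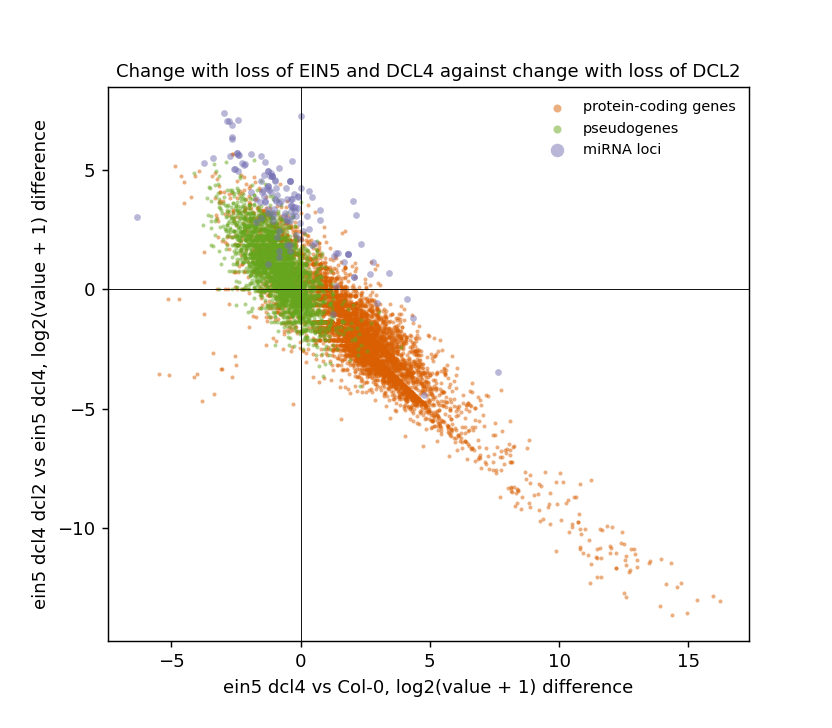
Each point is 1 of the tested miRNA loci, protein-coding genes or pseudogenes, with the log2(value + 1) difference of ein5 dcl4 against Col-0 on the x axis and of ein5 dcl4 dcl2 against ein5 dcl4 on the y axis. NIA1 lies at 16.21 and -13.04, and the 2 axes share the ein5 dcl4 libraries, which alone tilts the cloud downward.

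Against wild type, the triple mutant was lower at PPR genes and, under the deposited scaling, higher at miRNA loci. Of 16 tested PPR genes 12 were lower and 0 higher, with 14 lower when adjusted over the list alone. Of these AT1G63080 went from 1588 ± 16.4 to 34.0 ± 5.08 units (SD, n = 2), a log2 difference of -5.51 ± 0.23 at a limma adjusted p of 0.00362. AT1G62914 and AT1G63400 held 1 and 1 and 2 and 1 reads, against 1432 ± 19.2 and 1463 ± 31.0 units in Col-0, and AT1G62910 and AT1G63150 held 0 reads. The camera adjusted p was 1.06e-31, with an adjusted p = 0.0172 with an estimated correlation, and 0 members were higher in any rescaling tried or at an unadjusted p under 0.05.

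Of 132 miRNA loci 70 were higher and 1, MIR822, lower, and 120 and 1 when adjusted over the list alone. MIR319b rose by 3.73 ± 0.15, MIR157c, a regulator of SPL genes with 10.7% repeated 21-mers, by 2.77 ± 0.12 and MIR850 by 3.37 ± 0.16 on the log2 scale, each at a limma adjusted p of 0.00362. With equal miRNA totals the differences were -0.64 for MIR157c and -0.034 for MIR850, and with equal table totals -0.11 for MIR157c. None of these was called. MIR856 held 0 reads in Col-0 and 155 ± 17.6 units. Camera gave an adjusted p of 2.83e-72, with an adjusted p = 0.0172 with an estimated correlation. The count depended on scaling, since 80 loci were higher and 1 lower with trimmed-mean rescaling, 26 and 4 with equal table totals, and 3 and 1 with equal miRNA totals.

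The siRNA loci of the study did not pass the test. NIA1 differed by 3.17 ± 0.54 and NIA2 by 3.12 ± 0.53 on the log2 scale, with limma adjusted p of 0.0815 and 0.0814, while 3 of the 4 loci were higher when adjusted over the list alone and at an unadjusted p under 0.05. Their median log2 difference of 2.28 (3.34 with groups without reads at the floor) was 1.67 with trimmed-mean rescaling, 0.24 with equal table totals and -0.12 with equal miRNA totals. That list was the study's own choice and is not independent evidence. Of the nitrate genes, SMXL genes, RNA silencing and decay genes, miRNA target mRNAs and other phasiRNA-producing genes, 0 of 7, 8, 10, 22 and 11 were called by limma, with 3, 2, 3, 2 and 1 higher and 0, 0, 0, 2 and 1 lower at an unadjusted p under 0.05. With equal table totals 1, 0, 5, 12 and 11 were lower, and with equal miRNA totals 0, 0, 3, 8 and 9. Adjusted over the list alone, 3 nitrate genes, 2 silencing genes and 1 miRNA target were higher. Camera adjusted p were 0.0616, 0.335, 0.613, 0.0831 and 0.420. For the miRNA targets it was 0.0447 downward against protein-coding loci alone and 0.18 with an estimated correlation. For the siRNA loci of the study the camera adjusted p was 0.00764, with an adjusted p = 0.114 with an estimated correlation.

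Photosynthesis mRNAs were higher at 2 of 15 members, LHCB2.1 and LHCB2.2, with 15.3 ± 0.123 and 18.1 ± 3.91 units against 1.01 ± 0.384 and 1.05 ± 0.696, and 8 were higher when adjusted over the list alone. Of the exonic 21-mers of both 42.9% and 48.0% occur elsewhere, and with equal miRNA or table totals 0 members were higher and 3 lower. Camera gave an adjusted p of 1.28e-05, with an adjusted p = 0.114 with an estimated correlation. ATCG00020 was the 1 plastid gene called, higher by 3.07 ± 0.26 on the log2 scale, but it differed by -0.31 and was not called with equal miRNA totals. ATMG01130 was the 1 mitochondrial gene called, lower with 0 reads against 45 and 39. A read was worth only 0.185 and 0.257 units in Col-0, and a count of 0 allows up to 5.12 and 5.70 units in ein5 dcl4 dcl2. The size of this fall is thus uncertain. With trimmed-mean rescaling, equal miRNA totals and equal table totals 19, 50 and 88 mitochondrial genes were lower and 0 higher. The calls of ATCG00020 and ATMG01130 stood when adjusted over the list alone. Camera adjusted p were 2.22e-06 upward for plastid and 2.39e-08 downward for mitochondrial genes, each with an adjusted p = 0.0264 with an estimated correlation. With trimmed-mean rescaling 1 plastid gene was higher and 1 lower, and with equal miRNA or table totals 0 were higher and 5 or 13 lower. Pseudogenes were higher at 9 and lower at 4 of 2962 loci, and at 7 and 285, 0 and 1285, and 1 and 2317 with trimmed-mean rescaling, equal miRNA totals and equal table totals.

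In total 123 loci were higher and 34 lower in ein5 dcl4 dcl2 than in Col-0, with a median log2 difference of 0 over all loci. The counts were 153 and 489 with trimmed-mean rescaling, 4 and 1831 with equal miRNA totals and 62 and 3786 with equal table totals. Limma's voom on the recovered reads gave 4803 and 275, a prior without trend 16 and 12, a mean of at least 10 gave 278 and 114, and no filter 72 and 20. Voom adds the same fraction of a read to every count, which was worth more units in ein5 dcl4 dcl2 than in Col-0. Its median log2 difference over all loci was 1.93, so its count of higher loci partly follows from this. With a pseudocount of 0.1 or only these 2 genotypes 96 or 55 were lower, and with thinned reads 195 were higher. Without any 1 of the Col-0 or ein5 dcl4 dcl2 libraries limma called 0 loci, with 565 to 1558 higher and 146 to 558 lower at an unadjusted p under 0.05, and none of the 28 named loci called passed. In these fits, which leave 1 library in a genotype, AT1G63080 differed by -5.66 to -5.36 and MIR319b by 3.70 to 3.77, each at a limma adjusted p of 0.0632 to 0.103. Without ein5 dcl4 library a or b, 77 or 81 loci were higher, 9 of the 28 named loci no longer passed in either case, and without library b 57 were lower.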

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

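Limma's voom, equal table totals, thinned reads, the authors' adjusted p-values, the fit restricted to loci without a repeated 21-mer and list tests against protein-coding loci alone were chosen after the data were seen. No paired analysis was possible because the recovered libraries carry no replicate number, so the replicate block was not run. The count test intended for the recovered reads was not run either, and limma's voom was run on those reads. Counts are given as higher and lower, in the order ein5 dcl4 against Col-0, ein5 dcl4 dcl2 against ein5 dcl4, ein5 dcl4 dcl2 against Col-0, then the overlap. The reported counts were 4401 and 734, 1288 and 4087, 123 and 34, and 3743, and counts within 1.5 times of these are left out below.

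With a mean of at least 10, which tests 1852 loci, the counts were 647 and 305, 343 and 703, 278 and 114, and 610. Trimmed-mean rescaling gave 2016 and 2948, 2001 and 1970, 489 lower in the third comparison, and 1561. Equal miRNA totals gave 161 and 7755 in the second, 4 and 1831 in the third, and 6036. Equal table totals gave 1605 and 4738, 1910 lower in the second, 62 and 3786, and 1301. Without the prior's trend the third comparison gave 16 and 12. With only the 2 genotypes compared the second gave 631 and 2154, the third 55 lower, and the overlap was 2092. In the third comparison a pseudocount of 0.1 gave 96 lower, and no filter gave 72 and 20. Thinned reads gave 410 lower in the first, 657 higher in the second and 195 higher in the third. Voom gave 6826 higher in the first, 843 higher in the second and 4803 and 275 in the third. It adds the same fraction of a read to every count, which was worth more units in the mutants than in Col-0. Loci without reads were thus placed higher in the mutants. Under voom the median log2 difference of all loci was 3.49 in the first comparison and 1.93 in the third. The authors' deposited table gave 1635 and 76, 186 and 683, and 642. Restricted to the 733 tested loci without a repeated 21-mer, the counts were 348 and 32, 77 and 287, 29 and 1, and 267, from fewer loci by construction. Except for filters that change the number of loci tested, the fraction of a read added by voom and the scalings below, the cause was not tested.

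Without Col-0 library a the counts were 879 higher in the first, 613 and 2156 in the second and an overlap of 834, and without ein5 dcl4 dcl2 library a or b 846 or 842 were higher in the second. Leaving out each library in turn gave 767 to 4338 higher and 33 to 887 lower in the first comparison, 609 to 1219 and 2137 to 3311 in the second, 0 to 81 and 0 to 57 in the third, and an overlap of 737 to 3118. A lone library was taken to vary like the other genotypes. With an estimated correlation 0, 1 and 4 lists passed, against 8, 8 and 6, and against protein-coding loci alone, where the organelle and miRNA lists fall out, 5, 2 and 4. The estimate was 0.00917 for mitochondrial genes and -0.110 for the siRNA loci of the study, neither above the preset 0.01. In the first comparison their camera adjusted p still went from 3.57e-07 to 0.0669 and from 0.000453 to 0.0704. A larger correlation was thus not the reason for these 2 lists. Shares of the table total without 1 library ran from 65.5% to 68.2% for miRNA loci in Col-0, 3.69% to 4.80% in ein5 dcl4 and 96.0% to 96.4% in ein5 dcl4 dcl2. For protein-coding genes they ran from 14.6% to 15.9%, 94.0% to 95.1% and 1.35% to 1.54%, and for pseudogenes from 15.5% to 16.8%, 1.02% to 1.06% and 1.91% to 2.18%. Without the 10 largest loci miRNA loci held 35.3% in Col-0 and 84.6% in ein5 dcl4 dcl2, protein-coding genes 29.7%, 93.1% and 5.81%, and pseudogenes 31.5%, 2.43% and 8.31% in Col-0, ein5 dcl4 and ein5 dcl4 dcl2.

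The scalings moved the median log2 difference of all loci in the first comparison from 1.49 to -0.48 (trimmed mean), 1.54 (equal miRNA totals) and -1.63 (equal table totals), and a pseudocount of 0.1 or 5 moved it to 2.43 or 0.64. A mean of at least 10 gave -0.14 and no filter 0.77. Against a floor of 3 reads per library for groups without reads, the median log2 ratio of means was 1.39, -0.73 and 0.54 in the 3 comparisons. These medians were over 7243, 5228 and 5304 loci rather than all 11376 tested. Of 166 results for named loci 17 turned direction, each under 1 or 2 rescalings. In the first comparison equal table totals gave -0.44 for AT5G43740, -0.99 for AFB2, -0.94 for AT5G43730, -1.12 for AT1G51480, -0.70 for ATCG01050, -1.33 for ATCG00640, -2.19 for ATCG00020, -0.94 for ATCG00740, -1.56 for ATMG00513 and -1.13 for ATMG00180. Trimmed-mean rescaling gave -0.12 for ATCG00640, -0.94 for ATCG00020 and -0.35 for ATMG00513. In the second, equal miRNA totals gave -2.08 for ATCG00020. In the third, equal miRNA totals gave -2.24 for AFB2, -2.46 for AFB3, -0.64 for MIR157c, -0.034 for MIR850 and -0.31 for ATCG00020, and equal table totals gave -1.77 for AFB2, -1.98 for AFB3, -0.98 for AGO2 and -0.11 for MIR157c. These follow from the factor each rescaling applies to whole libraries. With 1 read worth 1.71 to 2.79 units in the mutants, differences near 1 unit were not detectable there.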

Other observations

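The tests of scaling on miRNA loci and on gains in ein5 dcl4, and the share of higher loci without a repeated 21-mer, were chosen after results were seen, and the settings with equal table totals, thinned reads and loci without a repeated 21-mer were chosen after the data were seen.

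The AGO1-bound pool was concentrated on few loci in each genotype. In ein5 dcl4, 3 loci made up at least 50% of the table total of each library and 60 and 59 loci made up 90%, against 725 and 625 loci for 90% in Col-0 and 17 in both ein5 dcl4 dcl2 libraries. MIR157a and MIR157b held the same reads in both ein5 dcl4 libraries, 311 and 207 each, so reads that match both appear to have been counted at both. MIR166e, MIR166f and MIR166g, among the largest loci, had nearly equal means of 124755, 124755 and 124885 units over the 6 libraries. Repeated counting may therefore raise the miRNA shares and the concentration on few loci.

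Loci higher in ein5 dcl4 than in Col-0 numbered 4401, and a read was worth more units in ein5 dcl4, under a scaling to an unstated total. Thinned to the same value per read, 3365 loci were still higher, which argues against unequal precision per unit as the whole cause. Thinning kept the deposited scaling, so it could not test unequal depth under another total. With equal table totals 1605 loci were higher. Of 655 tested protein-coding loci without a repeated exonic 21-mer 49.9% were higher (95% interval 46.0 to 53.8) against 55.4% of all 7833. That share argues against reads shared between related loci as the whole cause. Over 4 splits of the libraries into pairs, loci chosen in 1 pair exceeded pseudogenes in the other pair by a median of 7.11 to 7.20 on the log2 scale for gains of at least 5 and of 4.56 to 4.81 for gains of 1 to under 5 with at least 10 reads, which 1 factor per library cannot produce, although it could set the direction of single loci (of 4044 called gains under 5, 37 were called lower and 1248 still higher with equal table totals). With fewer than 10 reads the excess was 2.26 to 2.83, but the lower quartile in the other pair was 0 and 32.0% to 39.0% of these loci held no reads there in ein5 dcl4, so scaling and a gain in small RNA cannot be told apart for them. Loss of EIN5 and DCL4 stays open as a biological explanation and was not tested, since the 3 genotypes include no single mutant and the total behind the values is not given.

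The miRNA loci were higher in ein5 dcl4 dcl2 than in Col-0 under the deposited scaling. Their median log2 difference exceeded that of pseudogenes by 3.08, and by 2.97 to 3.14 over the 4 pairs of libraries, which 1 factor per library cannot produce, although it could set the direction of miRNA loci themselves. Less carry-over of RNA not bound by AGO1 might lower the background in ein5 dcl4 dcl2. Against miRNA loci the sums of pseudogenes, plastid genes and mitochondrial genes changed by -3.51, -1.38 and -4.19, a spread of 2.80. A carry-over common to the 3 classes would change them alike, so it cannot give this spread alone. All 3 classes fell, so carry-over as a part of the difference stays open. The 3 mutations stay open as a biological explanation and were not tested, since the genotypes include no single mutant and the total is not given.

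A hypothesis was that gene families with shared sequence make the largest gains in ein5 dcl4. Of 70 protein-coding loci with a gain of at least 10 on the log2 scale 8 held at least 5% repeated exonic 21-mers, against 1630 of 7763 others, an odds ratio of 0.486 (95% interval 0.200 to 1.02) with a two-sided Fisher's exact p of 0.0542. The test gave no excess of repeated sequence among these loci, and the interval leaves a lower share open.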
